A study of Drosophila melanogaster with 2 samples.

How the data were processed

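Chromatin from whole Drosophila melanogaster embryos, collected 0 to 12 h after egg laying, was immunoprecipitated with an antibody against Sin3A and sequenced (ChIP-seq). Sin3A is the scaffold protein of a conserved corepressor complex that carries a histone deacetylase. Per the labels' protocols, the material was crosslinked in 1.8% formaldehyde for 15 min and sonicated for 15 min, chromatin-bound antibody was recovered on Protein A beads, and an aliquot of the same chromatin served as the input. The series holds 1 ChIP sample, whose title joins replicates 1 and 2, and 1 input sample. A single peak list for the ChIP sample was analysed; the input was not analysed here as a data set of its own.

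Reads were aligned with Bowtie to the BDGP5 build, per the submitters' processing notes, and peaks were called with MACS, per the file header. The versions, the calling threshold, the way the 2 replicates were joined and the use of the input during calling are not given in the sources used here. For each peak the authors deposited a start, an end and a score. The scale of the score is not named in the file. Its lowest value, 50.05, lies just above 50. Such a floor is what a score made from a negative logarithm of a p-value and a threshold on it would give, so no ratios of scores are printed. The score was used only to rank, filter and compare peaks within this list. Read numbers and coverage were not given, so the sequencing depth behind a peak is unknown. Starts were taken as counting from 0, as in the BED format, and coordinates are printed counting from 1.

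No genome sequence or gene annotation of BDGP5 was used here. The gene table at hand describes Release 6, another build, and positions were not converted between builds. The 4 tests that need genes or sequence (peaks at promoters, feature classes, fixed gene lists and sequence words) were therefore left out, and regions are named by position instead of by gene.

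The tests, their alternatives and the rule for named regions were set before the data were examined, except where an analysis is described as added. The rule names the 20 peaks with the highest scores, the 5 widest peaks, the 5 windows of 100 kb with the most peak midpoints and the 5 longest gaps between neighbouring peaks. The peaks on each of the 6 arms (2L, 2R, 3L, 3R, X and 4) were compared with the arm's share of sequence by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 6 arms. The length of an arm was its span from the first to the last peak. The sequence total comprised the 6 arms and the heterochromatic sequences whose names end in Het. The Het sequences were also measured from first to last peak, so the 4 with a single peak counted only as that peak's width. They thus added very little to the total. Uextra, which collects unplaced sequence, belongs to no arm and was left out of that total. Clustering was the share of peaks with another peak midpoint within 5 kb on the same sequence. It was set against 1000 placements of as many midpoints, drawn uniformly over the span of each sequence (one-sided permutation test, smallest possible p 0.001). Placed midpoints had no width and could fall arbitrarily close together, unlike real peaks. Score and width were related by Spearman's rho with 10000 permutations (two-sided, smallest possible p 0.0001).

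Analyses added after the data had been seen were the comparison of median scores and widths between arms (10000 permutations of the arm names), the permutation of complete 1 Mb bins between the 5 large arms (10000 permutations, two-sided), the spacing of 100 kb windows and gaps under the 1000 placements, and the width of peaks at equal score. For the last, the peaks of 2L, 2R, 3L and 3R were divided into 10 equal groups by score. Each peak's width was given as a percentile among the reference peaks of its score group, and labels were permuted within score groups 1000 times. Each of the 4 large autosomal arms was compared with the other three in the same way. Peaks near the centromere and scores of neighbouring peaks (scores shuffled 1000 times within arms or, for close pairs, within 10 equal groups of peaks by width) were also examined; the ends of 2L, 3L and X and the starts of 2R and 3R were taken to face the centromere.

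All p-values describe the placement or ranking of peaks within 1 list. Peaks are not biological replicates, and with both replicates joined in 1 list no value has a replicate error. Intervals are 95% exact binomial (Clopper-Pearson) or exact Poisson intervals over peaks and cover counting error only. They, the binomial test and the permutations of arm names treat peaks as independent, so they understate the error where peaks cluster. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.

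The statistics were tested on simulated lists of 4034 peaks. Of 100 uniform lists, 7 were called clustered at p under 0.05, and all 100 lists in which 1 in 20 peaks had been moved next to another were called. Of 100 lists drawn by arm length, 6 had an arm called, and 2R was called in all 100 lists with 1.3 times as many peaks per Mb on 2R. The peaks of these lists were independent, without the clustering of the real list. The lists therefore do not give the error rate of the binomial test in these data. Of 40 random sets of autosomal peaks, 0 were called at equal score, while all 40 sets narrowed to 0.8 of their width were called. Random sets are not complete arms, and some large autosomal arms were called by this test in the real list. The 0 of 40 is therefore not the error rate of the width test for complete arms. Alternatives covered the higher-scoring part of the list, the 6 arms alone, joined neighbouring peaks, other distances, placement within 1 Mb bins, other arm lengths and the removal of the 5% widest peaks.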

Results

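The binding of Sin3A was mapped in whole embryos collected 0 to 12 h after egg laying. The data comprised 1 ChIP sample, with replicates 1 and 2 joined, and 1 input sample. The ChIP sample was represented by 4046 peaks on 12 sequences of the BDGP5 build. The peaks had a median width of 969 bp (quartiles 738 and 1336 bp, range 171 to 3686 bp) and a median score of 270 (quartiles 127 and 546, range 50.05 to 2483.68). The score is the authors' own value for each peak. No replicate error can be given for any peak, and the read depth is unknown.

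Nearly all Sin3A peaks, 4034 of 4046, lay on the 6 chromosome arms. They covered 4.35 Mb, or 3.68% of the 118 Mb spanned by peaks on these arms. The arm 3R held 991 peaks, 2R held 811, 3L held 775, X held 731 and 2L held 700. The small chromosome 4, which is rich in heterochromatin, held 26. Another 8 peaks lay on heterochromatic sequences outside the arms and 4 on unplaced sequence.

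The first comparison asked whether peaks were spread over the arms in proportion to sequence length. Density ran from 22.2 peaks per Mb on chromosome 4 to 38.6 on 2R, but none of the 5 large arms passed a test that allows for the variation between 1 Mb bins. Arm 2R held 1.13 times as many peaks as its length predicted (95% interval 1.06 to 1.20, adjusted p = 0.000834, exact binomial test). Arm 2L had 31.3 peaks per Mb and held 0.917 times the predicted number (interval 0.855 to 0.980, adjusted p = 0.0304, exact binomial test). The ratio of chromosome 4, 0.651 (interval 0.425 to 0.952), did not pass the threshold after adjustment (adjusted p = 0.0511, exact binomial test). The ratios of 3R (1.04, interval 0.985 to 1.10), 3L (0.964, interval 0.903 to 1.03) and X (0.956, interval 0.894 to 1.02) did not pass the test, with adjusted p-values of 0.222, 0.261 and 0.222. The exact binomial test treats peaks as independent, and they were not: over complete 1 Mb bins the variance of the peak count was 4.20 times its mean. When bins were permuted between the large arms, neither 2R (1.15 times the mean of the other arms, adjusted permutation p = 0.434) nor 2L (0.894 times, adjusted permutation p = 0.488) passed. Chromosome 4 was left out of that permutation, so its density was tested only with peaks taken as independent. Among the peaks with a score of at least 269.79, 2R was no longer called (ratio 1.09, adjusted p = 0.133, exact binomial test) and chromosome 4 was, with 3 of 2020 peaks (ratio 0.150, adjusted p = 4.59e-05). The calls also moved with the sequence total. With arm length counted from position 1, 2L was not called (ratio 0.945, adjusted p = 0.149, exact binomial test), while 3R (1.08, adjusted p = 0.0232, exact binomial test) and chromosome 4 (0.639, adjusted p = 0.0357, exact binomial test) were. With Uextra in the total, 2L turned to an uncalled 1.05, and 2R, 3R, 3L and X were all called above 1.

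Within arms, density varied from bin to bin. Over the 115 complete 1 Mb bins of 2L, 2R, 3L, 3R and X the median was 33 peaks. The highest count, 63, was found between 19 and 20 Mb on 2R, and the lowest, 5, between 0 and 1 Mb on the same arm.

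**Figure D1:**
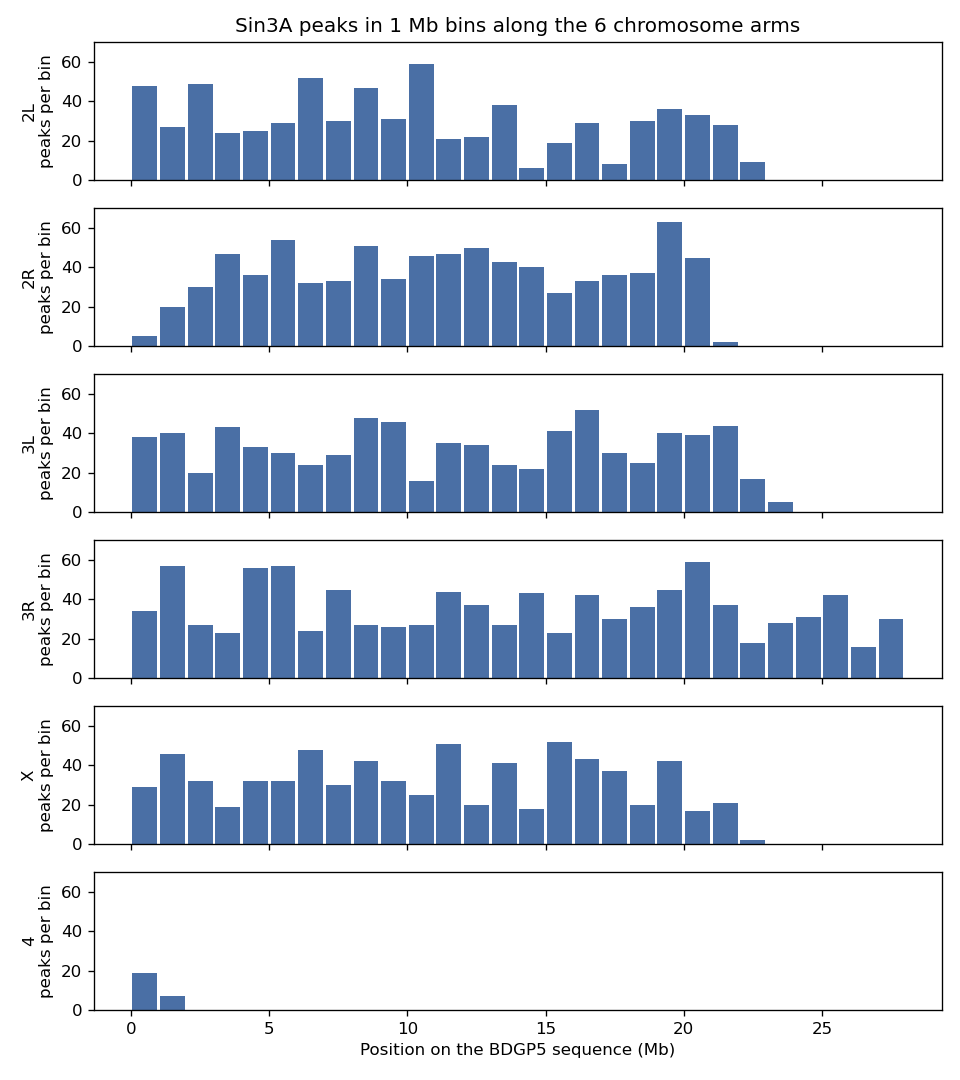
Number of Sin3A peaks (vertical axis) whose midpoints fall in each 1 Mb bin along the 6 chromosome arms (horizontal axis, position in Mb on BDGP5). The bins of 2R run from 5 peaks in the first to 63 between 19 and 20 Mb; the last bin of each arm is incomplete.

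The strongest peaks were found on each large arm. Of the 20 peaks with the highest scores, 5 lay on 3R, 5 on X, 4 on 2R, 3 on 2L and 3 on 3L, and 0 on chromosome 4. Their scores ran from 1801 to 2484, against a median of 270 in the list. All 20 were wider than the median peak, at 1096 to 3148 bp. The highest score, 2483.68, belonged to a peak of 2901 bp at chr3R from 11617796 to 11620696. The peak at chr3R from 22691811 to 22693731 followed with a score of 2454.64. The peak at chr3L from 871511 to 873155 scored 2327.14 and that at chr3R from 24160720 to 24162455 scored 2269.29. The strongest peak on 2L spanned positions 6479294 to 6481854 (score 2215.80) and the strongest on 2R spanned 5579303 to 5581414 (score 2047.99). On the X the strongest peak spanned 17780178 to 17781769 (score 2008.74). The X also held the narrowest of the 20, a peak of 1096 bp from 15032900 to 15033995 with a score of 1956.31.

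The widest peaks were a largely different set. The widest, 3686 bp at chr3R from 14067359 to 14071044, ranked 260 by score (1038.97). The next, 3413 bp at chr2L from 8380832 to 8384244, ranked 974 (563.64). A peak of 3230 bp at chr3R from 25881221 to 25884450 ranked 526, and one of 3188 bp at chr2L from 1979624 to 1982811 ranked 586. Only the fifth widest, 3148 bp at chr2L from 5980276 to 5983423, was also among the 20 strongest, at rank 16 (1869.94).

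The next comparison asked whether Sin3A peaks lay closer together than uniform placement would give. They did: 2410 of the 4042 peaks on sequences with more than 1 peak, or 59.6% (95% interval 58.1 to 61.1), had another peak within 5 kb. The 1000 uniform placements gave a mean of 29.0% and at most 31.5% (permutation p = 0.001, the smallest they can give). The median distance between neighbouring peaks was 8.08 kb, against a mean of 20.2 kb and a lowest value of 19.2 kb under placement. The share was above every placement on 2L (60.0%), 2R (57.5%), 3L (61.7%), 3R (61.5%) and X (58.3%), each with an adjusted permutation p of 0.0012. On chromosome 4 it was 34.6% (interval 17.2 to 55.7), against a placed mean of 19.0%, and did not pass the test (adjusted permutation p = 0.0949). The median distance there was 29.0 kb, against a placed mean of 31.005 kb (permutation p = 0.38). Of the 4028 pairs of neighbours on the arms, 414 were at most 500 bp apart. With these joined, 48.2% of the regions still had a neighbour within 5 kb, against a placed mean of 26.5%. Among the peaks with a score of at least 269.79, a list of lower density, the share was 27.3%, against a placed mean of 16.2%, and the median distance was 22.8 kb (permutation p = 0.001 for each, the smallest possible).

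**Figure D2:**
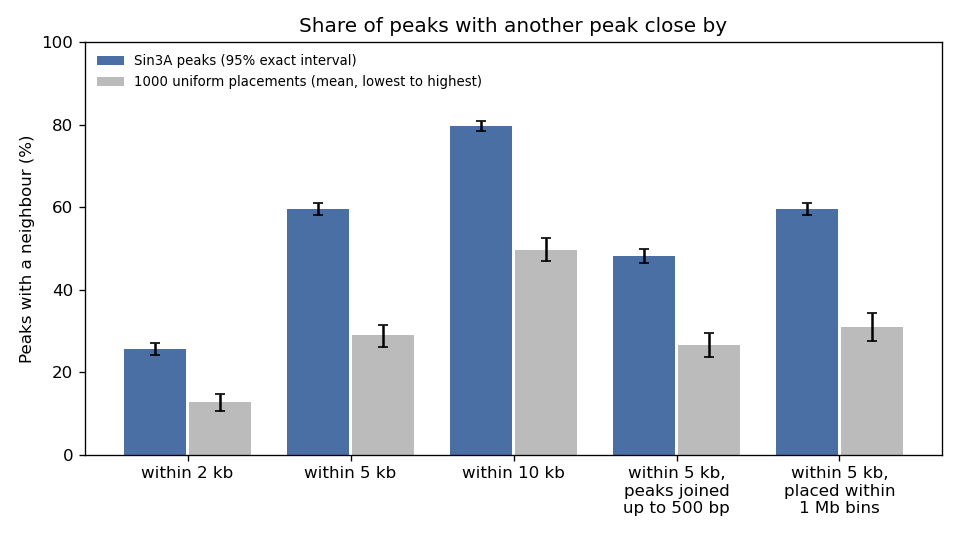
Share of Sin3A peaks with another peak midpoint within the stated distance (blue, with 95% exact binomial interval) and the share in 1000 uniform placements (grey, mean with the lowest and highest placement). For each of the 5 settings the observed share lies above the highest placement, for example 59.6% against 31.5% within 5 kb.

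The crowded and the empty stretches can be named. The window with the most peaks covered chr2R from 19900001 to 20000000, with 17 peaks, a median score of 211 and a highest score of 1017. On 2L the windows from 6900001 to 7000000 and from 10300001 to 10400000 held 15 peaks each. The peaks of the second were weak, with a median score of 121 and a highest score of 302. On the X the window from 19500001 to 19600000 held 15 peaks, with a highest score of 1717, and on 2R the window from 12000001 to 12100000 held 14. Of 1188 windows, 289 (24.3%) held no peak, while placement gave a mean of 39.9 empty windows and at most 60 (permutation p = 0.001, the smallest possible). The fullest windows of the placements held 9 to 18 peaks, and the count of 17 was hardly ever reached (permutation p = 0.002). These placements were uniform along each arm, and the clustering test had already rejected uniform placement. The window tests therefore describe the same departure and are not separate evidence. Placement that keeps the counts of larger bins was not run for windows.

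The longest stretch without a peak, 624 kb, lay on 2R from 617985 to 1241537, partly in the complete bin with the lowest count. It was followed by 574 kb on 2R from 15558720 to 16132239, 514 kb on 2L from 14491385 to 15005112, 511 kb on 3L from 18103455 to 18614148 and 503 kb on X from 20396372 to 20899118. Between midpoints the longest gap was 624 kb, and the longest gaps under placement ran from 191 to 478 kb (permutation p = 0.001, the smallest possible). The gap test used the same uniform placements as the window tests, so it is not separate evidence either.

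The last comparison related score to width. Stronger peaks were wider: Spearman's rho across the 4046 peaks was 0.690 (permutation p = 0.0001, the smallest possible). The median width rose from 640 bp in the lowest of 10 equal groups by score to 1589 bp in the highest. Within arms rho ran from 0.595 on chromosome 4 to 0.782 on the X. Peaks are not independent replicates, and score and width come from the same reads.

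The X and chromosome 4 stood apart from the large autosomal arms in this relation, in an analysis added after the data had been seen. X peaks had a median score of 308, against 265 for 2L, 2R, 3L and 3R together (adjusted permutation p = 0.0384), and a median width of 838 bp against 1010 bp, a difference of -172 bp (adjusted permutation p = 0.0003). Against the other autosomal arms, 2L (-60 bp, adjusted permutation p = 0.0319), 3L (-52 bp, adjusted permutation p = 0.0491) and 3R (74 bp, adjusted permutation p = 0.0032) also passed the test of width, with smaller differences. Among autosomal peaks of the same score group, the width of X peaks had a median percentile of 20.6. Each of the 4 large autosomal arms, set against the other three, lay between 43.8 and 55.5. Chromosome 4 peaks had a median width of 436 bp and a median score of 89.3. The difference in median score from the large autosomal arms did not pass the test (adjusted permutation p = 0.0774), while that in width did (-574 bp, adjusted permutation p = 0.0003). Only 3 of the 26 chromosome 4 peaks scored at least 269.79, whereas 2023 of all 4046 peaks did. The test of medians therefore does not show that chromosome 4 scores were like those of the other arms. The median width percentile of chromosome 4 peaks at equal score was 3.89. The percentiles of X and chromosome 4 were both outside all 1000 permutations (adjusted permutation p = 0.00233). Of the large autosomal arms, 3L (43.8, adjusted permutation p = 0.0035) and 2R (55.5, adjusted permutation p = 0.0112) also passed this test.

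**Figure D3:**
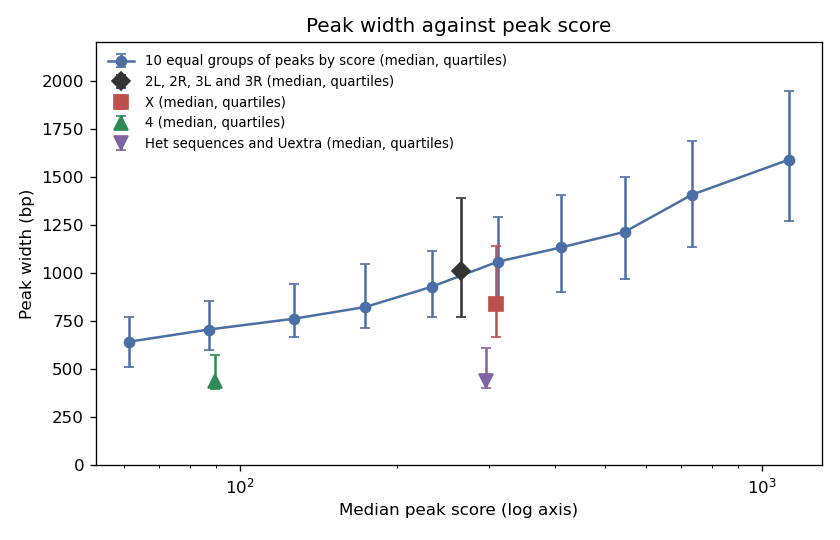
Median peak width in bp (vertical axis) against median peak score (horizontal axis, logarithmic) for 10 equal groups of all peaks by score (circles joined by a line) and for the peaks of 4 sets of sequences (other markers); bars span the quartiles of width. The X, chromosome 4 and the sequences outside the arms lie below the line, with median widths of 838, 436 and 437 bp.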

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

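The test of width at equal score was chosen after the widths had been seen. Peaks were also found outside the 6 arms that the comparisons use: 8 on the heterochromatic sequences (4 on XHet and 1 each on 2LHet, 2RHet, 3LHet and 3RHet) and 4 on Uextra, the collection of unplaced sequence. They are listed because the comparisons between arms leave them out; no number of peaks was predicted for these sequences. The 4 Uextra peaks were narrow, with a median width of 309 bp and a range of 213 to 403 bp, yet their median score of 367 lay above that of the whole list, 270.

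Narrow peaks off the large arms are the pattern most worth a second look. At equal score, the 12 peaks outside the arms had a median width percentile of 0.761 among autosomal peaks, and the 26 peaks of chromosome 4 had 3.89. Both lie below the 43.8 to 55.5 of the large autosomal arms and outside 1000 permutations (adjusted permutation p = 0.00233), which argues against the explanation that width follows score. Repeats that leave few uniquely placed reads, short unplaced contigs, and a different extent of Sin3A binding in heterochromatin may each give narrow peaks. These stay open, since neither the sequence nor the read coverage was analysed here.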

How the results depend on the processing

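Clustering within 5 kb, the shorter median distance and the relation of score to width kept their direction and their call under every alternative run over all arms together; taken arm by arm, clustering was not called on chromosome 4 (34.6%). The share of peaks with a neighbour ran from 25.6% within 2 kb to 79.8% within 10 kb. Among the peaks with a score of at least 269.79 it was 27.3% within 5 kb, against a placed mean of 16.2%, with a median distance of 22.8 kb against 39.1 kb under placement. Spearman's rho ran from 0.443 among the higher-scoring peaks to 0.782 on the X, in a split by arm that was also added. The shares per arm depended more on the settings. Restricting the list to scores of at least 269.79 left 2023 peaks by construction, ended the call of 2R (ratio 1.09), brought a call of chromosome 4 (0.150) and turned the uncalled ratio of X to 1.04. The next settings were chosen after seeing the data. Counting arm length from position 1 ended the call of 2L (0.945) and brought calls of 3R (1.08) and chromosome 4 (0.639), because the Het sequences and chromosome 4 then take a larger part of the total. Counting Uextra, with 4 peaks over a long span, raised the ratio of every arm by construction: the call of 2L ended as it turned to 1.05, 3L and X turned to called ratios of 1.10 and 1.09, and 3R became called at 1.19. Permuting complete 1 Mb bins between arms, in place of the binomial test, ended the calls of 2R (1.15) and 2L (0.894), because bin counts vary more than independent peaks would. Chromosome 4 was left out of that permutation, so its calls rest on the binomial test alone. Joining peaks up to 500 bp apart, added after seeing the data for the arm shares, clustering and rho, left 3632 regions and changed no call. Joining book-ended peaks changed nothing, since no peaks overlapped or touched. Alternatives for promoters, gene lists, feature classes and sequence words, and the count of transcription start sites per arm, were not run, because no BDGP5 annotation or sequence was used here. Leaving out a replicate was not possible with both joined in 1 list, the depth is unknown, and binding that gave a score under 50.05 is outside the list.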

Other observations

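Placement within 1 Mb bins was set before the data were examined; the tests of joined peaks, X peak width, neighbouring scores, close pairs and the centromere side were chosen after the data had been seen. The ends of the arms that face the centromere held few Sin3A peaks on most arms. The 1 Mb of the peak span next to the centromere held 5 peaks on 2R, against 40.3 per Mb on the rest of the arm (ratio 0.124, exact Poisson interval 0.0403 to 0.290). The ratio was 0.357 on X (interval 0.184 to 0.624), 0.385 on 3L (interval 0.205 to 0.658) and 0.532 on 2L (interval 0.310 to 0.852). On 3R, with 34 peaks, it was 0.955 (interval 0.661 to 1.33). The Poisson interval lay below 1 on 4 of the 5 arms and included 1 on 3R. Such intervals treat peaks as independent, whereas the variance of counts over complete 1 Mb bins was 4.20 times their mean. They are therefore too narrow to tell on which arms a drop next to the centromere applies. On X and 3L the counts next to the centromere, 12 and 13, were below those of every complete 1 Mb bin of the same arm, whose lowest were 17 and 16. The 5 peaks on 2R were likewise the lowest count of that arm, and the longest gap between peaks lay partly in the same stretch. On 2L the count of 17 was not the lowest: away from the centromere, 2L held 6 peaks between 14 and 15 Mb and 8 between 17 and 18 Mb.

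Peaks in close pairs scored lower than peaks farther apart. Where neighbouring midpoints lay under 2 kb apart, the weaker partner had a median score of 109 and the stronger 302 (546 pairs). Between 5 and 20 kb apart these medians were 164 and 535 (1382 pairs). The differences were -54.98 for the weaker and -233 for the stronger partner. Peaks that do not overlap can lie so close only if their widths average under 2 kb. Most peaks are below that width (upper quartile 1336 bp), so this limit is loose. Narrower peaks scored lower across the list. Shuffling scores among peaks of like width gave a median difference of -43.0 for the weaker partner (permutation p = 0.0549) and -168 for the stronger (permutation p = 0.002), so most of both differences goes with width. On the arms, 414 pairs of neighbours were at most 500 bp apart, and the comparison was not repeated with these joined. Whether splitting of broad regions by the peak caller contributes to the lower scores was therefore not tested. A hypothesis that neighbouring peaks have alike scores was not borne out: Spearman's rho over 4028 pairs was 0.0338, inside the range of 1000 shuffles within arms, -0.0544 to 0.0574 (permutation p = 0.0569).

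For the clustering of peaks, neither explanation that could be tested accounted for all of the pattern. With peaks up to 500 bp apart joined, the share with a neighbour within 5 kb fell from 59.6% to 48.2%, and the placed mean from 29.0% to 26.5%. The 48.2% was still above the 29.5% of the highest of 1000 placements. Splitting of broad regions by the peak caller at such gaps may thus contribute but is not the whole cause. Wider gaps were not joined. When each 1 Mb bin kept its count, placement reached at most 34.4%, against 59.6% observed, so differences in density between such bins are not the whole cause either. With both changes together the share was 48.2% against a placed mean of 28.3%. Gene density on a finer scale may contribute and was not tested, and the design names no biological contrast.

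X peaks combined higher scores with smaller widths. Width follows score cannot be the whole cause, since the median width percentile of X peaks at equal score was 20.6, below the 43.8 of the lowest large autosomal arm. It was 20.99 among the peaks with a score of at least 269.79 and 20.82 after joining peaks up to 500 bp apart. The read depth of the X may differ from that of the autosomes if male embryos, with a single X, were among those collected, and the score alone (median 308.36) cannot settle it without coverage. A difference in the extent of Sin3A binding between X and autosomes is a hypothesis that stays open, as does a difference in the spacing of genes.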
